A study of Rattus norvegicus with 4 samples.

How the data were processed

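Total RNA from cultured rat testicular peritubular myoid cells was profiled on 4 one-colour Agilent arrays, 2 from cells given testosterone and 2 from control cells. Per the labels' protocols, the RNA was amplified from an oligo-dT primer, labelled with Cy3 and hybridised to the Agilent 4x44k rat design. Each sample's group and replicate number came from its title. The labels do not say whether the replicates came from separate animals or cultures, so the p-values measure only the spread between these arrays, which may be technical.

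Per the file headers, the scanner files were written by Feature Extraction 11.5.1.1, and the submitters' processing notes name Agilent Feature Extraction 10.5. The deposited scanner files give each spot's processed signal, mean signal and local background as an intensity on a linear scale, together with flags for spots well above background, saturated spots and outlier spots. Per the file headers, probe positions refer to the rat build rn4. The deposited table of the whole series holds the authors' values on the log2 scale. Set against the scanner values over 40749 probes printed once on the array, each column equalled the log2 processed signal minus a constant of 8.79 and 8.63 for testosterone and control replicate 1, and of 8.38 and 8.55 for replicate 2. Column medians were -3.61, -3.62, -3.34 and -3.45 in the same order. Scale, centring and direction of the authors' table were thereby known, since genes were not centred and no sign was turned.

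All 4 arrays were on 1 slide and in 1 scan, so no slide or scan could be tested as a batch, and the slide as a block did not apply. Each array held 45018 spots, of which 43379 were not controls, for 41012 probes. Between 63.5% and 68.2% of these spots were well above background, and the number of arrays limits the precision. The quality metrics in the headers gave a median coefficient of variation of replicated spots of 9.52% on control replicate 1, against 5.25% to 5.53% on the other arrays. For spike-in spots that coefficient was 11.0% on control replicate 1 and 4.47% to 4.90% on the others. Control replicate 1 was the only array whose header verdict asked for evaluation.

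The main values were log2 processed signals minus each array's 75th percentile over non-control spots. Control spots and outlier-flagged spots were left out, saturated spots were kept, and spots of one probe were averaged. A probe entered the tests when it was well above background on both arrays of at least 1 group, which 25881 probes did. The brightest probe stood for each gene, which gave 22017 genes and unnamed transcripts, 10896 of them with a symbol in the reference table. Of 3178 genes with more than 1 tested probe, 74 had probes whose differences lay over 1 apart on the log2 scale and 1458 had probes with both signs.

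Probes were named through the reference gene table of assembly GRCr8, used for names and not for coordinates. By accession 11121 probes were named, by symbol 5129 and by an older symbol 3392. The other 21370 kept the name in the scanner file. A match through a secondary accession or an older symbol was accepted only when the gene lay on the probe's chromosome.

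Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment, called at an adjusted p under 0.05), over the 2 testosterone and 2 control arrays with no covariate. A second count took genes at least 2-fold apart whose groups did not overlap. With 2 against 2 arrays an exact permutation test cannot give a 2-sided p under 0.333, so none is reported. Before the data were examined, 28 gene lists were fixed, 21 for pathways and 7 for cell types, and 27 of them had the minimum of 5 measured genes. Those lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. With an estimated correlation camera draws on the few residual degrees of freedom of 4 arrays, so hardly any list could pass. A list it leaves uncalled is therefore not argued against by it. Fry tests whether the genes of a list move one way on balance, without comparing them with other genes.

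Genes were named by a rule fixed at the same point as the lists. It takes the 12 largest differences in each direction among genes well above background and unsaturated on all 4 arrays with groups apart, called genes first, under reference symbols only. It adds up to 4 genes per direction detected on both arrays of one group and neither array of the other, up to 4 members of each list, and fixed genes that include Srd5a1, Fkbp5, Gdnf, Acta2 and Myh11 where measured. Not every gene the rule takes is given in the text. Genes detected in one group alone were given as "at least N-fold", setting the bright group's mean against, per array, the higher of the dim probe's signal and the lowest signal well above background, which averaged -5.59 on the log2 scale. No probe carried the name Acta2 or Myh11. Cx3cl1 and Gnl3 were chosen after their values were seen.

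The procedure was tested on simulated arrays with the real means and limma's moderated spreads of the 22017 genes, drawn independently for each gene and array. The simulation held no difference between replicate numbers, no area of low readings and no correlation between genes. Its rates may therefore not hold for these arrays. With the spread as measured, 0 of 50 genes changed 2-fold were called, 33 of 50 changed 4-fold, 45 of 50 changed 8-fold and 50 of 50 changed 16-fold. There were 13 false calls among the unchanged genes. A simulated list moved as a whole was called, and 0 of the fixed lists left unmoved were. Its shift was larger than any list's mean difference between testosterone and control with all 4 arrays. Smaller shifts of a list were not simulated.

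Alternatives covered normexp background correction with quantile normalization, quantile normalization alone, median scaling, the authors' table, filters on dim probes, a floor, flagged spots, the choice of probe, 2 variance models, array weights, the replicate number as a block, each array left out, other thresholds and other list tests. After the data were seen, alternatives were added that left out an area of low readings on control replicate 1. A dropped spot was defined as one at least 2 below the lowest of the other 3 arrays on the log2 scale, with those 3 well above background. The added alternatives left out either all tiles of 10 rows by 5 columns that held 2 or more dropped spots, or all of columns 57 to 85.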

Results

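Peritubular myoid cells are the contractile cells that surround the seminiferous tubule and respond to androgen. Cells isolated from the testes of 40-day-old rats were cultured for 4 days with defined growth factors and given 1e-07 M testosterone in pulses, and control cells formed the other group. The series asks which genes testosterone induces in these cells. Gene expression was measured with 2 arrays per group. Levels are log2 processed signals relative to each array's 75th percentile, with means ± SD over n = 2 arrays and 95% intervals from limma.

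No gene passed the test in either direction. Of 22017 genes and unnamed transcripts tested, 0 were higher and 0 lower with testosterone at an adjusted p under 0.05 in limma, the smallest adjusted p being 1.00. At an unadjusted p under 0.05 there were 174, which is 0.790% of those tested, 113 with a positive and 61 with a negative difference. Both testosterone arrays lay above both control arrays for 1329 genes (6.04%) and below them for 2003 (9.10%), where a chance order of 4 arrays gives 16.7% each way. The median half-width of the 95% interval was 0.64 on the log2 scale. These shares are lower than chance would give. The arrays within each group also differed by replicate number, which widens the spread behind the tests and intervals. The absence of calls therefore does not show that few genes changed. With the replicate number as a block, 616 genes (2.80%) had an unadjusted p under 0.05 in limma, with 0 called. That share is also lower than chance would give. Across genes well above background on all 4 arrays, the testosterone difference in number 1 correlated at -0.128 with that in number 2. Without the tiles that held 2 or more dropped spots the correlation was -0.161, so the differences did not run together.

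Srd5a1, which encodes a 5-alpha-reductase that converts testosterone to dihydrotestosterone, differed by -0.27 (-1.19 to 0.64; chromosome 17, 3878645 to 3878704, rn4). Fkbp5, a co-chaperone of steroid receptors and a known androgen target in other tissues, stood at 4.82 ± 0.18 and 4.80 ± 0.02 (SD, n = 2). Its difference was 0.02, with an interval from -0.51 to 0.55 (chromosome 20, 6637600 to 6637659). Gdnf, a growth factor for spermatogonial stem cells, was also bright at 4.82 ± 0.42 and 5.03 ± 0.46 (SD, n = 2) and differed by -0.20 (-1.13 to 0.73; chromosome 2, 57403890 to 57403949). None of these 3 genes passed the test. A probe described in the file as a predicted transcript similar to aortic smooth muscle actin was not well above background on any array. That probe does not carry the name Acta2, so the level of Acta2 was not measured. A pair of probes described as smooth muscle myosin heavy chain (Myosin-11) differed by 0.07 and -0.06.

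Of 23 measured androgen-responsive genes, 6 had a positive and 17 a negative difference, and 0 passed the test, over all genes or adjusted over the list alone. The mean difference was -0.08 and the list did not pass limma's camera (adjusted p = 0.288). Zbtb16, a transcription factor induced by glucocorticoids and androgens, differed by -0.34 (-0.84 to 0.16). Tsc22d3, a glucocorticoid-induced leucine zipper protein, differed by -0.20 and Elk4 by -0.24. Ndrg1 differed by 0.33 (-0.27 to 0.92). The 17 measured steroid receptor and steroid metabolism genes had 9 positive and 8 negative differences, with Sts, steroid sulphatase, at -0.32 (-0.83 to 0.20).

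Most of the largest positive differences came from genes that read low on control replicate 1 alone. Control replicate 1 was the lowest array for all 12 genes and at least 1 below the other 3 arrays for 10 of them, and 11 of the 12 probes lay in columns 57 to 85 of the array. Rnps1, an RNA-binding splicing protein, stood at 3.28 ± 0.01 with testosterone, at -0.96 on control replicate 1 and at 3.15 on control replicate 2. Efhd2, Nras, G3bp2, Mib1, Mtx2, Fez1 and Epha4 also read lowest on control replicate 1, with differences of 2.13, 1.72, 1.70, 1.44, 1.44, 1.40 and 1.37. Calb1, Daam2, Arfrp1 and Pik3c2a completed the 12, at 1.25, 1.16, 1.06 and 1.02. Apart from Pik3c2a, each of their intervals included 0. All 12 missed the test.

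**Figure D1:**
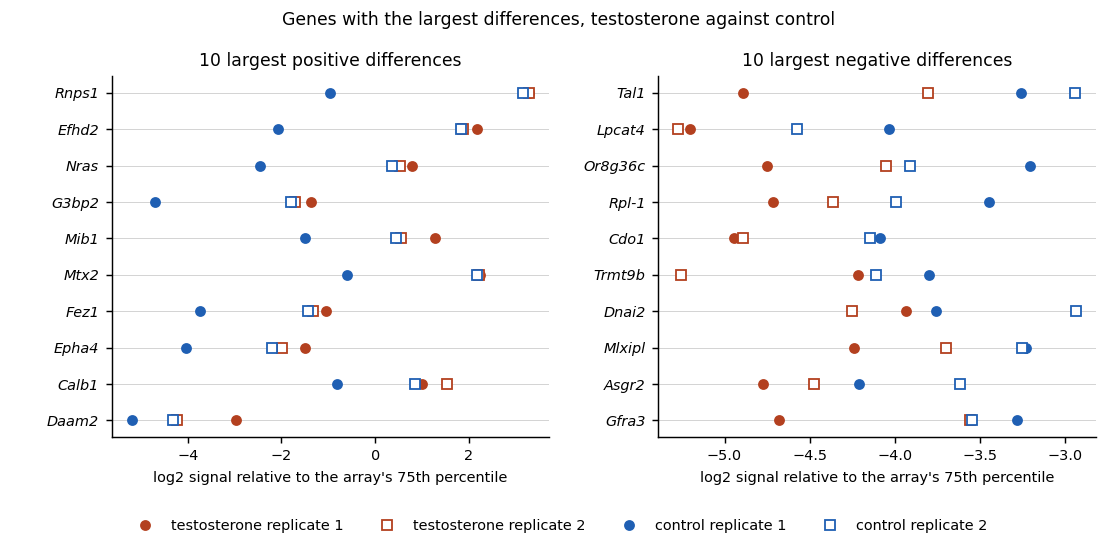
Log2 signal relative to the array's 75th percentile (horizontal axis) for the 10 genes with the largest positive and the 10 with the largest negative difference, 1 symbol per array (filled for replicate 1, open for replicate 2). Control replicate 1 is the lowest array for all 10 genes on the left, at -0.96 for Rnps1 against 3.15 on control replicate 2.

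On control replicate 1, 222 spots were dropped, against 21 on testosterone replicate 1, 5 on testosterone replicate 2 and 2 on control replicate 2. Columns 57 to 85 held 219 of the 222. Examples among bright genes were Rps19, a ribosomal protein, at -5.07 on control replicate 1 and 7.41 on control replicate 2 (its probe was saturated on 3 arrays), and Gnl3, a nucleolar GTPase, at -6.99 and 5.08. Cx3cl1, a membrane-bound chemokine, read -5.68 and 6.59 with one probe and 0.58 and 0.36 with another.

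**Figure D2:**
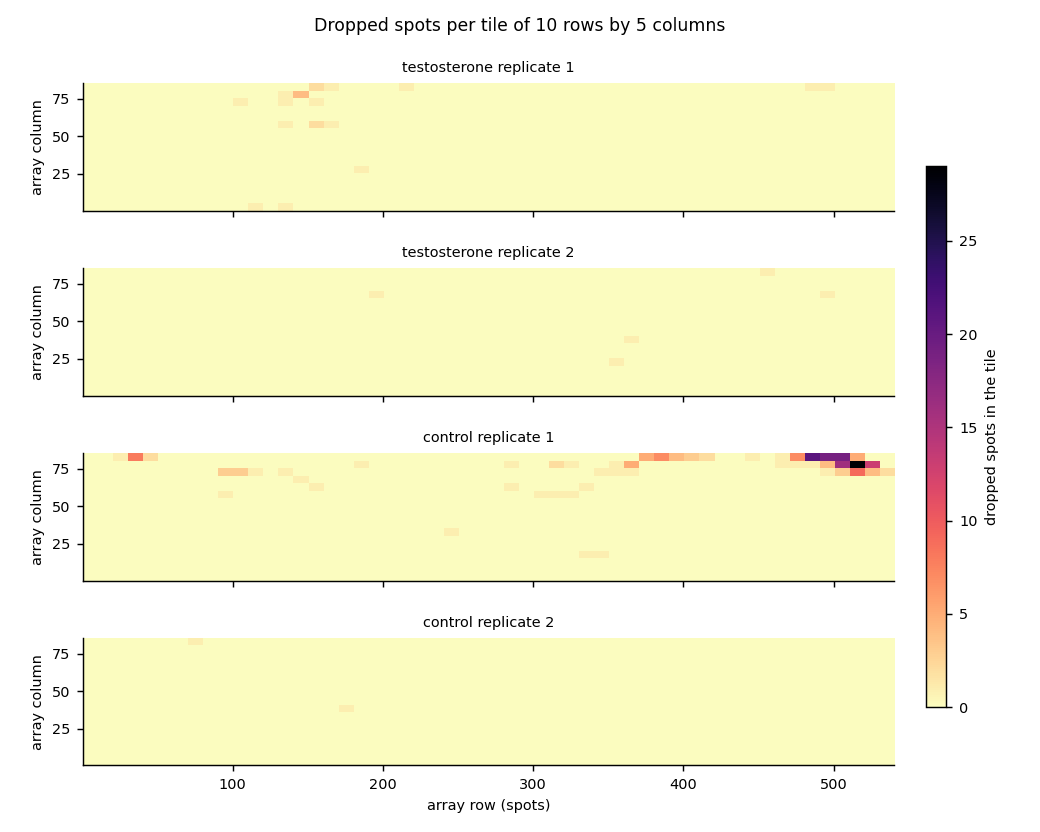
Number of dropped spots in each tile of 10 array rows (horizontal axis) by 5 array columns (vertical axis), 1 panel per array. The 222 dropped spots of control replicate 1 lie mostly along its high-numbered columns, and the other arrays have 21, 5 and 2.

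The largest negative differences among genes well above background on all arrays were smaller, with group means between -5.24 and -1.96. Cdo1, cysteine dioxygenase, stood at -4.92 ± 0.04 with testosterone and -4.12 ± 0.04 in control (SD, n = 2), a difference of -0.80 (-1.28 to -0.32; chromosome 18, 40921357 to 40921416). Tal1, a haematopoietic transcription factor, differed by -1.25 (-2.38 to -0.12) and Lpcat4, a lysophospholipid acyltransferase, by -0.94 (-1.62 to -0.25). Or8g36c, Rpl-1, Trmt9b, Dnai2, Mlxipl, Asgr2, Gfra3 and Doxl1 lay between -0.84 and -0.69. None of these genes passed the test. Their sizes depended on the processing. Over the alternatives with all 4 arrays kept, the differences of Cdo1, Tal1 and Lpcat4 shrank to as little as -0.21, -0.38 and -0.21.

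By size alone, 124 genes were at least 2-fold higher and 33 at least 2-fold lower with groups apart. Of the 124, 102 (82.3%) lay in columns 57 to 85, which held 33.4% of the genes tested, and 17 of the 33 did. Without those columns 22 were higher and 16 lower. With normexp and quantile normalization the counts were 20 and 0.

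Some genes were detected on both arrays of 1 group only, 97 with testosterone and 59 in control. The largest bounds with testosterone were those of Iqch, Igf2bp3, Igsf9 and Pde11a, at least 4.64-fold, 3.61-fold, 2.49-fold and 2.04-fold higher. In control they were Tssk5, Or1o1, Npbwr1 and Slc6a2, at least 2.14-fold, 2.11-fold, 2.07-fold and 1.65-fold higher. Several bounds rested on 1 array. Without testosterone replicate 1 that of Igf2bp3 was 1.04-fold and that of Igsf9 1.51-fold, without testosterone replicate 2 that of Iqch was 2.83-fold, and without control replicate 2 that of Tssk5 was 1.42-fold. None of these 8 passed the test (adjusted p = 1.00 in limma), and the Igf2bp3 probe lay in a tile with dropped spots.

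One fixed list passed camera. The split of the 4 arrays by neither testosterone nor replicate number also had 1 list called higher. Of 28 measured hypoxia and glycolysis genes, 24 had a positive and 4 a negative difference, and the mean difference was 0.15 and the median 0.12 (adjusted p = 0.0106 in limma's camera). It was not called with an estimated correlation (adjusted p = 0.943, the value of every list tested) or by fry (adjusted p = 0.996), nor without a detection filter (adjusted p = 0.187). Pdk1, a kinase that inhibits pyruvate dehydrogenase, stood at 0.04 ± 0.18 with testosterone and -0.61 ± 0.75 in control (SD, n = 2), a difference of 0.65 (-0.45 to 1.74) that was 0.12 without control replicate 1 and 1.17 without control replicate 2. The Pdk1 probe lay in columns 57 to 85 and read lowest on control replicate 1. Adm, the vasodilator peptide adrenomedullin, differed by 0.49 (-0.53 to 1.52), and Egln3, an oxygen-sensing prolyl hydroxylase, by 0.33 (-0.29 to 0.95). Pfkfb4, a regulator of glycolysis, differed by -0.17 (-1.16 to 0.82). The probes of Eno1 and Pgam1 were saturated on 3 and 4 arrays, so the sizes and signs of their differences were not measured exactly. Both testosterone arrays lay above both controls for 6 of the 28, and 0 passed the test, over all genes or adjusted over the list alone. The list's mean on each array was 2.81 and 3.27 with testosterone and 2.74 and 3.03 in control. Leaving out 1 array moved the mean difference to between -0.08, without testosterone replicate 2, and 0.38, without testosterone replicate 1, and the list was also not called without control replicate 1 (0.01). Such fits leave the replicate numbers unbalanced, and between same-numbered arrays the mean was 0.06 for number 1 and 0.24 for number 2.

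**Figure D3:**
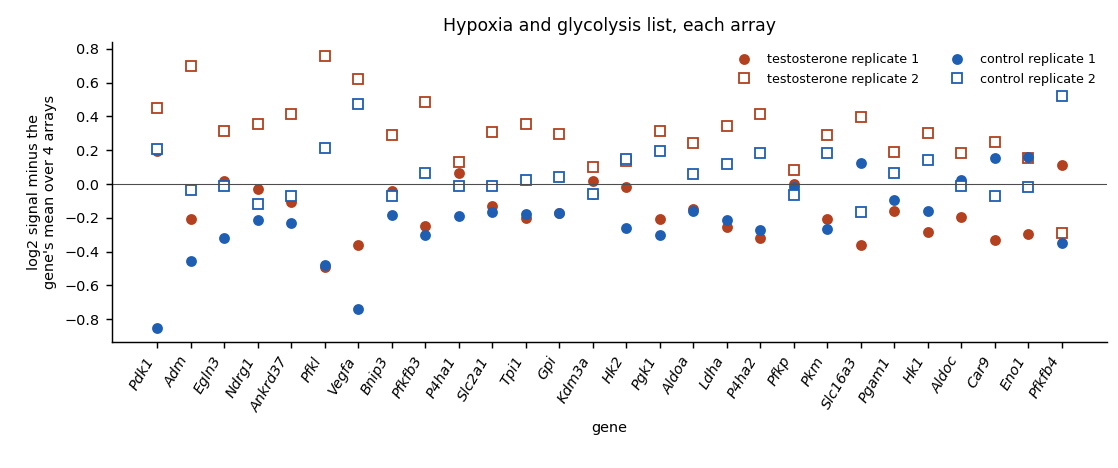
Each measured hypoxia and glycolysis gene (horizontal axis) on each array, as log2 signal minus the gene's mean over the 4 arrays (vertical axis), ordered by the difference of the groups. Differences run from 0.65 for Pdk1 to -0.17 for Pfkfb4.

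The contractile and matrix genes that mark peritubular cells did not pass camera as lists. Of 17 smooth muscle contractile genes 6 had positive and 11 negative differences (adjusted p = 0.705 in camera), with Myl9, a myosin light chain, at -0.28 (-0.80 to 0.24) and Actg2, gamma smooth muscle actin, at 0.58 (-0.53 to 1.69). The Actg2 probe also lay in columns 57 to 85, and its difference was 0.03 without control replicate 1 and 1.12 without control replicate 2. Of 29 extracellular matrix and basement membrane genes 15 were positive, and of 23 matrix proteases and inhibitors 16 were. Lamb2 differed by 0.89 (-0.79 to 2.57) and Adamts4 by 0.34 (-0.23 to 0.91), the Lamb2 probe lying in a tile with dropped spots.

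With all 4 arrays no list of secreted factors or signalling genes passed camera. Positive differences were found for 14 of 25 secreted growth factors and cytokines, 8 of 17 IGF signalling and binding proteins, 13 of 19 TGF-beta and BMP response genes and 11 of 19 Wnt and Notch genes. Nrtn differed by -0.40 and Igf2 by -0.23, and Id4, an inhibitor of differentiation, by 0.33 (-0.18 to 0.84). Pappa, a protease of IGF-binding proteins, differed by 1.69 with an interval from -1.16 to 4.54, and its probe lay in such a tile too.

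Among metabolic and stress lists, 5 of 26 cholesterol and fatty acid synthesis genes had positive and 21 negative differences. The mean of that list was 0.05 with every measured member and -0.08 without the tiles that held dropped spots, and its median was -0.07 (adjusted p = 0.319 in camera). Srebf1 differed by -0.21 and Srebf2 by -0.21. Positive differences were found for 10 of 28 mitochondrial respiratory chain genes, 25 of 35 cytosolic ribosomal protein genes, 10 of 20 antioxidant genes, 7 of 20 unfolded protein response genes, 14 of 28 cell cycle genes, 7 of 17 circadian clock genes and 2 of 14 retinoid genes. Among response genes, 22 of 24 inflammatory cytokine and chemokine genes, 10 of 24 interferon response genes and 15 of 28 immediate early genes were positive. The mean of the inflammatory list was 0.11 and ran from -0.53 to 0.75 when 1 array was left out, with calls in both directions at the preset correlation and 0 with an estimated one. Those fits leave the replicate numbers unbalanced, and between same-numbered arrays the mean was 0.04 for number 1 and 0.18 for number 2. Il6 differed by 0.43 (-1.69 to 2.56) and Fos by -0.41 (-1.34 to 0.53).

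Markers of other cell types were detected, and with all 4 arrays and no covariate none of their lists passed camera. Germ cell markers had 9 positive and 9 negative differences among 18 measured (mean 0.11, adjusted p = 0.793), and the mean ran from -0.68 without testosterone replicate 2 to 0.90 without testosterone replicate 1. Leaving out 1 array unbalances the replicate numbers, and between same-numbered arrays the mean was 0.07 for number 1 and 0.14 for number 2. Sertoli cell markers had 7 of 14 positive, Leydig cell markers 6 of 14, macrophage and leukocyte markers 5 of 19 and fibroblast and interstitial markers 5 of 16. Endothelial markers were negative in 10 of 10 (mean -0.23, adjusted p = 0.288 in camera), with Vwf, von Willebrand factor, at -0.36 (-1.09 to 0.38). Between same-numbered arrays their mean was -0.37 for number 1 and -0.10 for number 2. The list was called lower with the replicate number as a block, and without control replicate 1 or testosterone replicate 2 (means -0.45 and -0.58). Without testosterone replicate 1 the mean was 0.11. Of 4 measured erythroid markers 1 was positive, too few for the list test. Tyrobp, a macrophage adaptor, was bright at 5.18 ± 0.30 and 5.39 ± 0.45 (SD, n = 2).

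**Figure D4:**
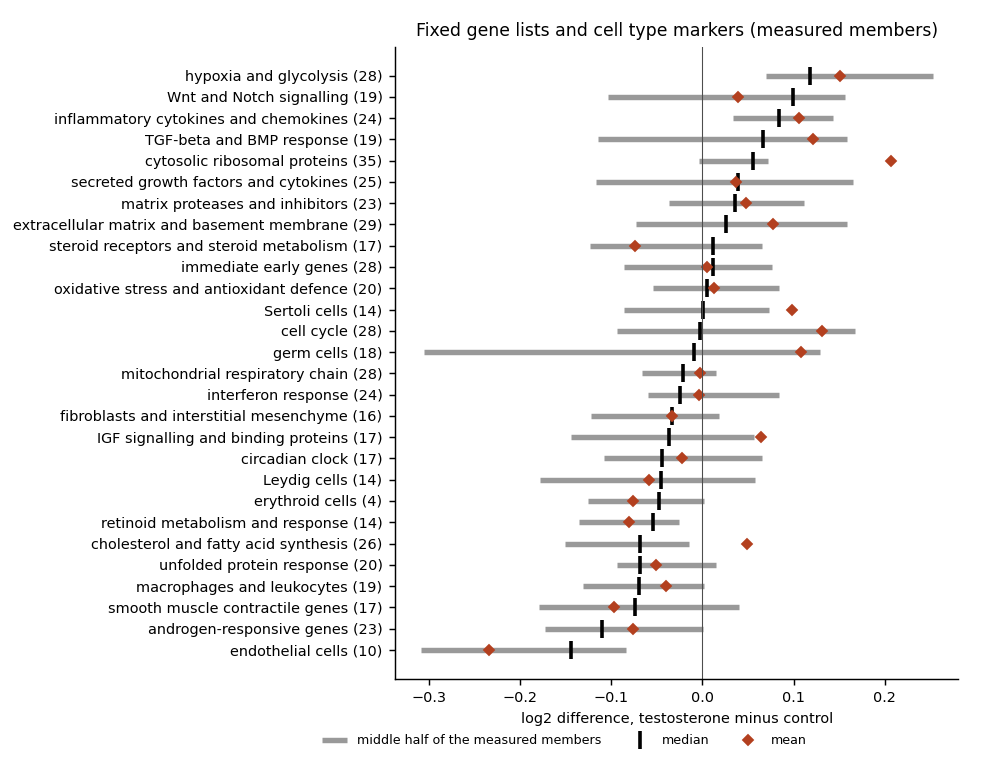
Mean, median and interquartile span of the log2 difference, testosterone minus control (horizontal axis), over the measured members of each fixed list, with the number of members in parentheses. The hypoxia and glycolysis list has a mean of 0.15 and the endothelial list one of -0.23. The ribosomal protein list has the highest mean, 0.21, which is 0.04 without the tiles that held dropped spots.

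Apart from hypoxia and glycolysis, the 26 lists tested had adjusted p-values from 0.288 to 0.909 in limma's camera, and 0 of their genes passed the test over all genes or adjusted over the list alone. Mean and median differed in sign for the steroid receptor, IGF, cholesterol, cell cycle and germ cell lists, and camera's direction was opposite to the mean for the secreted growth factor, IGF and cholesterol lists. Several list means were lower without the tiles that held dropped spots. The ribosomal protein mean was 0.21 with them and 0.04 without, and the cell cycle mean 0.13 and 0.02. For the TGF-beta and BMP, Sertoli cell and IGF lists the means with them were 0.12, 0.10 and 0.06. Without them these were 0.02, -0.004 and -0.02.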

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

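The alternatives that left out the damaged area were chosen after seeing the data, and the others before. With all 4 arrays kept, limma called 0 genes in either direction under every alternative. The block on the replicate number also called 0, with 616 genes at an unadjusted p under 0.05 against 174 without it. Both counts are lower than chance would give. Deviations from the group means correlated at 0.471 between same-numbered arrays. The labels do not say that the numbers mark a shared culture, so the arrays were not treated as paired. Under the block 1 list was called lower, the endothelial markers (adjusted p = 0.0105), also with the damaged tiles left out (1), and no other list call changed. With an estimated correlation camera did not call that list in either fit (adjusted p = 0.965 and 0.987), which few residual degrees of freedom made almost certain. Under the block the correlation estimated for the hypoxia and glycolysis list was 0.302, which reflects only the signs of the genes' deviations. Leaving out 1 array gave 0 to 35 genes higher and 0 lower, where the lone array was assumed to vary like the pair. All 35 were called without control replicate 2 and lay in the damaged tiles.

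The counts of 124 and 33 genes at least 2-fold apart moved most. They were 20 and 0 with normexp and quantile normalization, 543 and 252 with no detection filter, 29 and 4 with probes well above background on all 4 arrays, and 83 and 12 with a floor. At least 1.5-fold gave 295 and 111, and at least 3-fold 50 and 10. Leaving out 1 array gave 107 higher (without control replicate 1) to 641 (without testosterone replicate 1) and 105 lower (without control replicate 2) to 304 (without testosterone replicate 2), partly because 3 arrays part more easily. Leaving out the damaged tiles gave 85 and 30, columns 57 to 85 gave 22 and 16, and the tiles with the stricter filter 15 and 3. The cause was not tested for the other shifts.

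The hypoxia and glycolysis list was not called with no detection filter (0 lists), an estimated correlation (0) or fry (0). Leaving out 1 array gave 0 to 3 lists higher and 0 to 3 lower, the most without testosterone replicate 1 and control replicate 1 in turn. The hypoxia and glycolysis list was lost without control replicate 1 or testosterone replicate 2, and the endothelial list was called lower without the same arrays (means -0.45 and -0.58). The inflammatory list was called in both directions, higher without testosterone replicate 1 (adjusted p = 0.00890) or control replicate 2 (0.00248) and lower without control replicate 1 (0.00122). The secreted growth factor list was called lower without control replicate 1 (mean -0.23). The ribosomal protein list was called higher without testosterone replicate 1 (mean 0.39), with the genes in the damaged tiles kept. With an estimated correlation 0 lists were called in these fits, which cannot speak against the calls, since too few residual degrees of freedom were left. Over those fits the mean ran from -0.080 (without testosterone replicate 2) to 0.38 for hypoxia and glycolysis, from -0.53 to 0.75 for inflammatory cytokines and chemokines and from -0.23 to 0.30 (without control replicate 2) for secreted growth factors and cytokines. Of 146 named genes, none passing the test, 52 changed sign when 1 array was left out, and 13 under another setting. Of 27 lists 22 and 11 did. Signal over background limits the dim genes, since 4.99% of genes outside the tiles were not well above background on all 4 arrays.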

Other observations

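The tests of the 2-fold excess, by germ cell markers and by the correlation within the hypoxia list were chosen after the results were seen (camera with an estimated correlation was chosen earlier, with the lists), as were all comparisons of arrays by replicate number.

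The replicate number parted the arrays more than testosterone did. Between the arrays numbered 2 and those numbered 1, limma called 469 genes, 378 higher and 91 lower on number 2, against 0 between testosterone and control and 0 for the remaining split of the 4 arrays. That remaining split had 314 genes at an unadjusted p under 0.05 in limma, against 174 for testosterone. At the preset correlation camera called 1 list higher in each of these 2 splits. Between the numbers the calls were 812 higher and 322 lower with the damaged tiles left out, and 1538 and 743 with probes well above background on all 4 arrays as well. This many calls points to a structure of the samples other than testosterone, and the 4 arrays allow only 3 such splits, so an exact test could not go under 0.333. Germ cell transcripts were higher on the arrays numbered 2, with 7 of 18 measured markers called and a mean difference of 1.54 (adjusted p = 0.00172 in limma's camera, 0.758 with an estimated correlation). Tnp1 and Tnp2, the transition proteins of spermatids, stood at 1.59 ± 0.003 and 0.49 ± 0.03 on number 2 and at -3.11 ± 0.44 and -4.36 ± 0.62 on number 1 (SD, n = 2), which is 26.0-fold and 29.0-fold higher. Prm1, a protamine, was 7.30-fold and Fabp9, a sperm lipid-binding protein, 12.1-fold higher.

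Inflammatory genes parted the same arrays, with 12 of 24 list members called higher on number 2 and a mean difference of 1.21 (adjusted p = 2.6e-09, 0.758 with an estimated correlation). At the preset correlation camera also called the hypoxia (adjusted p = 0.00415), extracellular matrix (0.0130), ribosomal protein (0.0130), secreted factor (0.0325) and interferon (0.0353) lists higher and the circadian clock list lower (0.0438). With an estimated correlation camera called 0 lists (adjusted p from 0.758), though few residual degrees of freedom left it almost unable to call any. Complement C3 was 10.7-fold, the chemokine Ccl12 9.73-fold and the phospholipase Pla2g2a 7.81-fold higher. Mmp7, a matrix protease, went the other way, at -0.84 ± 0.07 on number 1 and -4.67 ± 0.36 on number 2 (SD, n = 2), as did Sycp3l2, named after a meiotic protein, at 0.04 ± 0.02 and -4.80 ± 0.39, and Il1rn, the interleukin 1 receptor antagonist, at 4.87 ± 0.05 and 3.63 ± 0.16. Among macrophage markers 3 were called lower on number 2, C1qa, C1qb and C1qc at -1.03, -1.15 and -1.04, and 1 higher, Adgre1 at 1.00. These genes were named after their values were seen.

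For this pattern, leaving out the damaged tiles raised the calls from 469 to 1134, so those 1134 lay outside the tiles. Genes low on control replicate 1 alone spread the arrays numbered 1 apart and could hardly be called. The rise in calls therefore cannot weigh on low readings as a source of large differences. At least 2-fold with the numbers apart, 993 genes were higher and 197 lower on number 2. Without the tiles those counts were 846 and 194. A trend with signal level stays open, with a Spearman correlation across genes of -0.119, between the bounds set beforehand. Carry-over of germ cell RNA in the cultures behind the arrays numbered 2 may account for the germ cell part and stays open, since the called markers prompted it. The 11 markers not called had medians of 0.248 with testosterone and 0.156 in control. They were picked by missing this same comparison, which keeps their differences small, so they cannot weigh on carry-over. Over all 18 the medians were 1.26 and 1.02, those of Sertoli, Leydig and macrophage markers at most 0.18, with single macrophage markers moving both ways, and those of endothelial markers 0.67 and 0.14. Carry-over leaves the inflammatory genes and the higher Sycp3l2 on number 1 unaccounted for, and the replicate number also follows the place on the slide (positions 1 and 2 against 3 and 4), which the design does not separate from the culture, and no biological explanation was tested.

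The excess of genes at least 2-fold higher over lower with testosterone (124 against 33) may come in part from damage to the control replicate 1 array beyond the tiles. Among genes outside the tiles with no dropped spot, 72.7% of the 77 higher genes lay in columns 57 to 85 against 31.5% of all such genes, a ratio of 2.31, and 46.4% of the 28 lower genes did. The tiles are defined by low spots, so the 39 higher genes inside them are no test. Dim probes stay open: with the tiles left out, 82.4% of the 85 higher genes were not well above background on all 4 arrays against 4.99% of all genes, but a large difference brings a dim gene under that limit by itself, and only 1 of the 2-fold genes, against 84 higher and 30 lower below it, had a mean level above the median. A response to testosterone in some genes stays open.

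The higher hypoxia and glycolysis list is not accounted for by the damaged tiles, since its mean was 0.151 without them (adjusted p = 0.00535; with all 4 arrays kept, the alternatives ran from 1.25e-05 to 0.996). That its genes may move together between cultures remains a candidate explanation, since the correlation between them estimated from the arrays was 0.735, against the preset 0.01. It was the highest of the 27 lists tested (median 0.080). The estimate ran from 0.392 without either testosterone array to 0.857 without either control array. With the replicate number as a block it was 0.302, below the antioxidant (0.800) and ribosomal protein (0.778) lists. These fits leave so few residual degrees of freedom that the estimate reflects only the signs of the genes' deviations. Such estimates are not comparable with 0.735, and their order ranks no list. The adjusted p of 0.943 with an estimated correlation in camera is no test of that explanation, as every list had that value. All 28 members were also higher on the arrays numbered 2, by a mean of 0.38. The estimate of 0.735 draws on these same differences within the groups, so they are not separate support. An effect of testosterone stays open.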
